A study of Mus musculus with 16 samples.

How the data were processed

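The files hold 16 two-colour Agilent oligonucleotide arrays of mouse genomic DNA (tail, C57BL/6). Each pairs 1 mouse with a reference male of the same colony, and each mouse has 2 arrays with the dyes exchanged. Per the labels, DNA was extracted with an automated tissue kit and labelled with the Agilent array CGH protocol. Per the file headers, images were processed with Feature Extraction 10.7.1.1 and the grid is annotated on build mm9. The scanner files' deposited log10 ratio is red over green processed signal. Processed signals are deposited as an intensity per channel, background-subtracted, spatially detrended and scaled by a linear dye factor, per the file headers. The median spot and background signals used for normexp are an unprocessed intensity, per the file headers. The deposited series table holds log2 ratios, and its scale and direction were found by setting each column against the scanner ratio of the same array. Its correlation with the scanner's red over green ratio was 0.992 to 0.998 with the reference in red and -0.989 to -0.998 with the mouse in red, so it runs reference over mouse. Its column medians ran from -0.0068 to 0.015, and the origin of this small shift, and so its centring, stays unknown.

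Ratios were turned to mouse over reference from the dyes in the labels and given as log2 of the processed signals, with each array centred on its autosomal median. No loess or quantile normalization was applied. Control spots (6745 per array) and spots marked as outliers by the image software (at most 0.035% of spots) were left out, no spot was saturated, and 966371 spots gave 950749 probes after averaging repeat spots. Repeat spots had a within-array SD of 0.092 on the log2 scale. The 2 arrays of a mouse were averaged into 1 profile and count as 1 replicate. Sire and dam are 1 animal each, and the 6 progeny are separate animals. The signal-to-noise ratio per array, the files' measure of depth, lay between 32.5 and 57.0 in green and between 26.4 and 60.7 in red. The spread of probe-to-probe differences was 0.207 to 0.232 on the parents' arrays and 0.169 to 0.205 on the progeny's. Single-orientation profiles carried a probe-specific dye effect: the 2 orientations of a mouse correlated at -0.168 to -0.385 over autosomal probes, and dye averaging removes it. The labels state the dyes, and X and Y of the dam give the direction.

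An autosomal probe counted as aberrant at an absolute log2 ratio of at least 0.5 on both arrays toward the same side. Intervals were runs of 3 to 1000 neighbouring autosomal probes with a score (sum of z over the square root of the number of probes) of at least 6, a mean of at least 0.3 and at least 0.2 with the same sign on each array. The noise SD came from neighbouring probes. Calls of different mice that overlapped reciprocally by a share of 0.5 formed 1 region, and a mouse carried it at a mean of at least 0.2 with the same sign on both arrays. Backgrounds were the same scan on the dye-direction track and, chosen after seeing the data, on 5 shuffles of the autosomal probe order. Each background was scored against the noise SD of its own track. Each progeny-only region was set against each parent with 10000 random runs of as many probes, taking the larger p of the 2 parents and Benjamini-Hochberg adjustment. Exact sign-flip, permutation and binomial tests were two-sided. Two-sided permutation p values double the smaller tail, and counting absolute differences was added after the results were seen.

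The planned gene-level tests could not be made, since the files name no genes and the gene table used here is of another build; coordinates were not converted. Autosomal 100-kb windows of at least 2 probes took their place, tested with limma 3.58.1 (R 4.3.3; lmFit and eBayes, Benjamini-Hochberg) as an intercept over 8 mice and as progeny minus parents. The gene lists and their tests were not run. In each family class, the text names the 8 regions with the highest score, and of windows the 10 with the largest absolute log2 ratio among those past the threshold in the same direction in every mouse. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

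The scan was tested on simulated data. In Gaussian tracks with planted intervals it made 0 calls outside them and recovered 96.0% of 3-probe and 100.0% of 10-probe intervals at 0.55. At -0.3 it recovered 13.5% of 3-probe and 80.0% of 10-probe intervals. In shuffled real profiles, scored against the noise SD of the unshuffled profiles, it made 793 calls outside the planted intervals over the 8 mice. In 23614 simulated windows against the reference, 92% of 0.05 differences and 10 unchanged windows were called, and in those of progeny minus parents 4 unchanged ones. Alternatives were normexp background correction (offset 50, on median signals since the planned mean signals were not used here), ratios not centred, each dye orientation alone, the series table, only probes well above background, outlier spots kept, a running median over 1000 probes subtracted, other thresholds for probes, calls, carriers and overlap, single probes, window medians, scan day as a random block, and leaving out each mouse. Planned choices were made before the data were examined. The custom arrays and quantitative PCR of the wider study were not analysed here.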

Results

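Genomic DNA from the tails of 8 C57BL/6 mice of 1 family was compared with DNA of a reference male of the same colony by array comparative genomic hybridisation, which measures copy number as the ratio of 2 labelled DNA samples at each probe. The family held 1 sire, 1 dam and 6 progeny. Each mouse was hybridised on 2 arrays with the dyes exchanged, so that 16 arrays gave 1 dye-averaged profile per mouse. The series title speaks of male mice given gamma rays at 1 mGy per day for 400 days, whereas the design text calls the sire and the dam not irradiated. The names of all 8 mice also carry 1mGy, without saying which animals were exposed. The exposure of the sire therefore stays unclear, whereas for the dam the title, which speaks of males, does not contradict the design text. The comparisons are between mice and the reference, and between progeny and parents, not between doses. The arrays held 950749 distinct probes, of which 950622 lay on autosomes at a median spacing of 2053 bp. The spread between neighbouring probes of the dye-averaged profile was 0.14 log2 units in the sire, 0.13 in the dam and 0.10 to 0.11 in the progeny. Sire and dam were scanned on the same day and the progeny on 3 other days, so that scan day and generation cannot be separated. The number of arrays limits the precision, since each parent was a single animal.

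Whole-chromosome dosage showed no gain or loss of an autosome in any of the 8 mice, and X and Y levels that fell at those of the sire or at those of the dam. The median log2 ratio of each of the 152 autosome and mouse combinations lay between -0.00 and 0.01. On the 68 X probes the sire had a median log2 ratio of -0.02 and the dam 0.93, with SDs between the 2 dye orientations of 0.06 and 0.01. On the 23 Y probes the sire had -0.05 and the dam -2.38, with SDs of 0.19 and 0.21. Progeny 1 and 2 had X medians of -0.03 and -0.00 and Y medians of -0.00 and -0.01. Progeny 3, 4, 5 and 6 had X medians of 0.92, 0.90, 0.93 and 0.92 and Y medians of -2.30, -2.21, -2.52 and -2.27. Normexp background correction brought the Y medians of the dam and of progeny 3 to 6 most of the way to the reference level. It also lowered their X medians, so the size of these ratios depends on how background is handled. The labels do not give the sex of the progeny, and they were not grouped by it. No interval on X departed from the mouse's own X median in any mouse under the scan used for the autosomes. That scan needs runs of at least 3 probes, and X had only 68 against 950622 on the autosomes. Short intervals like those called on autosomes could therefore hardly be found on X, and their absence is not shown.

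**Figure D1:**
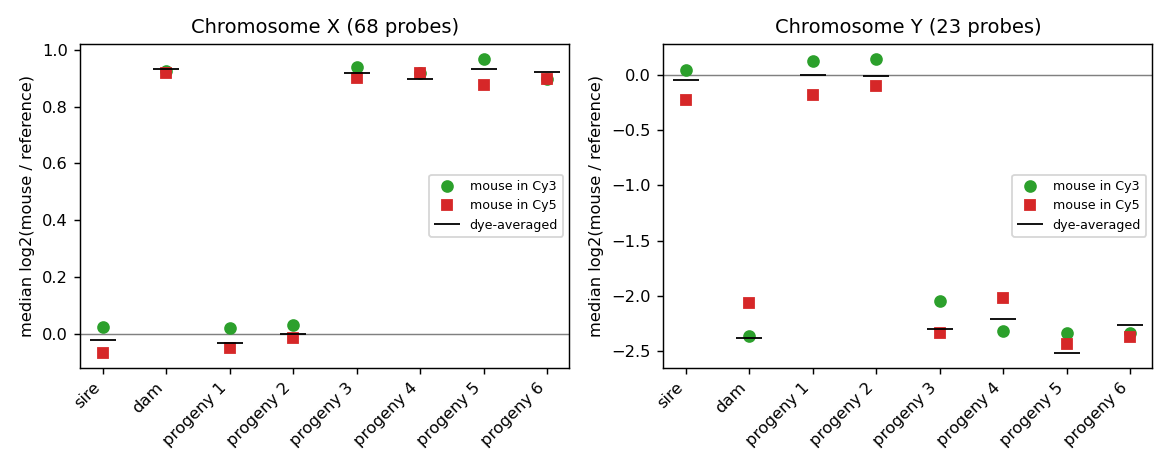
Median log2 ratio of mouse over reference on X and Y for each mouse, with the 2 dye orientations as points and the dye-averaged median as a bar. The dam lay at 0.93 on X and at -2.38 on Y, and the sire at -0.02 and -0.05.

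The most extensive difference within the family was a gain on chromosome 4 from 101110482 to 101270535 (mouse build mm9), which covered 74 probes and 160.1 kb. The sire had a mean log2 ratio of 0.96, the dam of -0.03, and the 6 progeny of 0.55 ± 0.01 (SD, n = 6), with 0.54 to 0.56 in the single animals. The interval was called in the sire and in all 6 progeny with the same first and last probe. The 2 dye orientations of the sire gave 0.96 and 0.96. The 74 probes on either side had means between -0.01 and 0.03 in all 8 mice. No gene was assigned, since the files name no genes and the gene table used here belongs to another build.

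**Figure D2:**
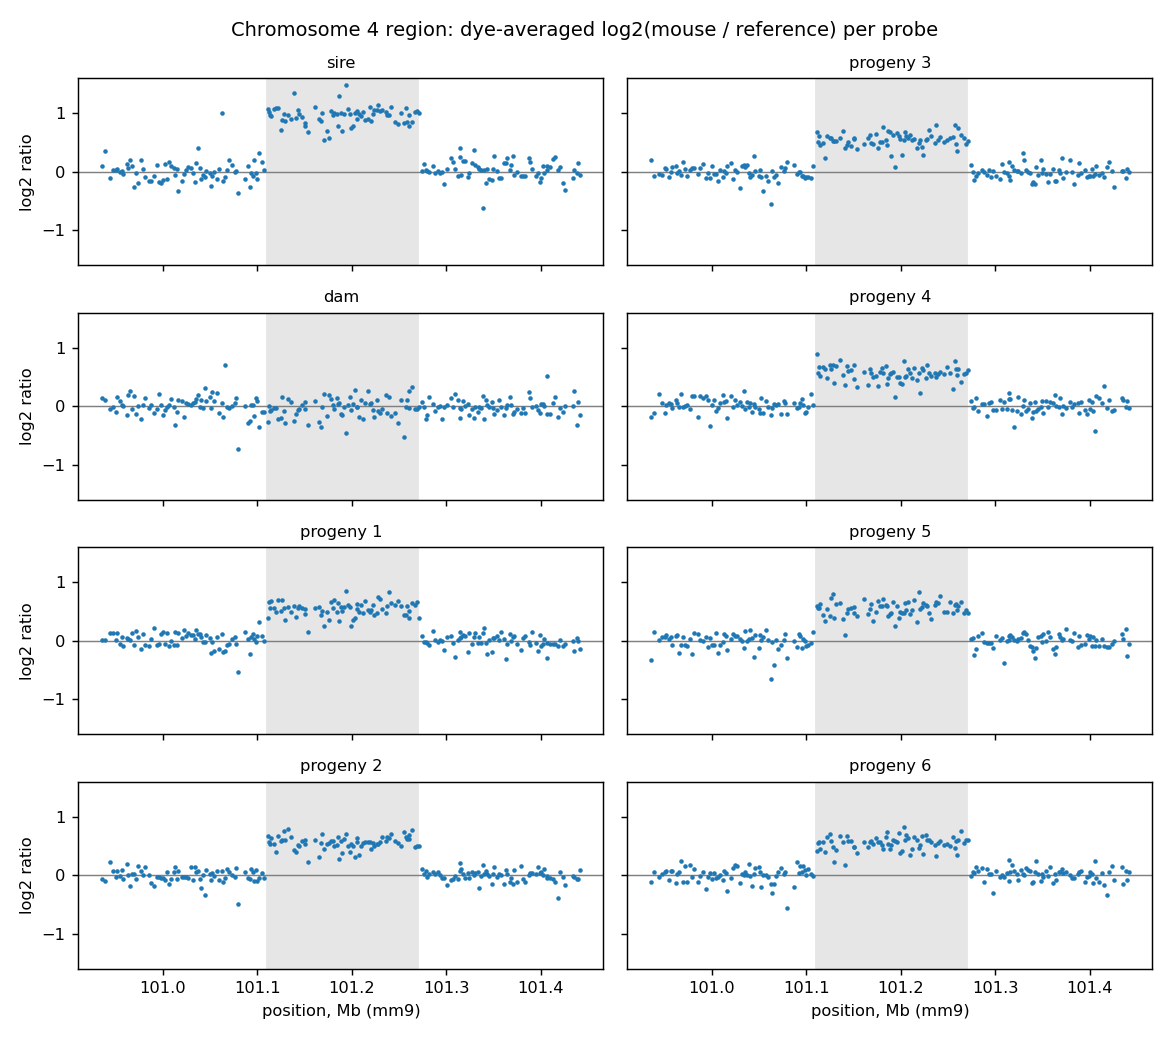
Dye-averaged log2 ratio of each probe around the chromosome 4 region (grey, mm9 position in Mb) in the 8 mice. The sire lay at 0.96 inside the region, the progeny at 0.54 to 0.56 and the dam at -0.03.

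In all 8 mice, 2 regions differed from the reference, on chromosomes 14 and 13. On chromosome 14, from 53459150 to 54278038 over 78 probes, every mouse lay below the reference, with a mean log2 ratio of -0.28 in the sire, -0.30 in the dam and -0.26 ± 0.03 in the progeny (SD, n = 6). These ends are those of the call in progeny 6. The longest call ended between 53954595 and 53994906 in the sire and progeny 1 to 5, and at 54181712 in the dam. Shorter losses were called past that end from 54058301 in the sire, 54112403 in progeny 1 and 4 and 54223715 in progeny 2. The 100-kb window from 54100001 had a mean of -0.26 over the 8 mice. Progeny 5 had a called gain of 0.30 over 5 probes from 54220927 to 54278038. Over 3 equal parts of the region the 8 mice had means of -0.32 ± 0.02, -0.32 ± 0.04 and -0.16 ± 0.08 (SD, n = 8), with -0.03 in progeny 5 over the last part. On chromosome 13, 3 probes from 95707465 to 95712034 lay above the reference, at 0.89 in the sire, 0.56 in the dam and 0.70 ± 0.14 in the progeny (SD, n = 6). The single reference animal is part of every ratio, so its own spread is left out.

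**Figure D3:**
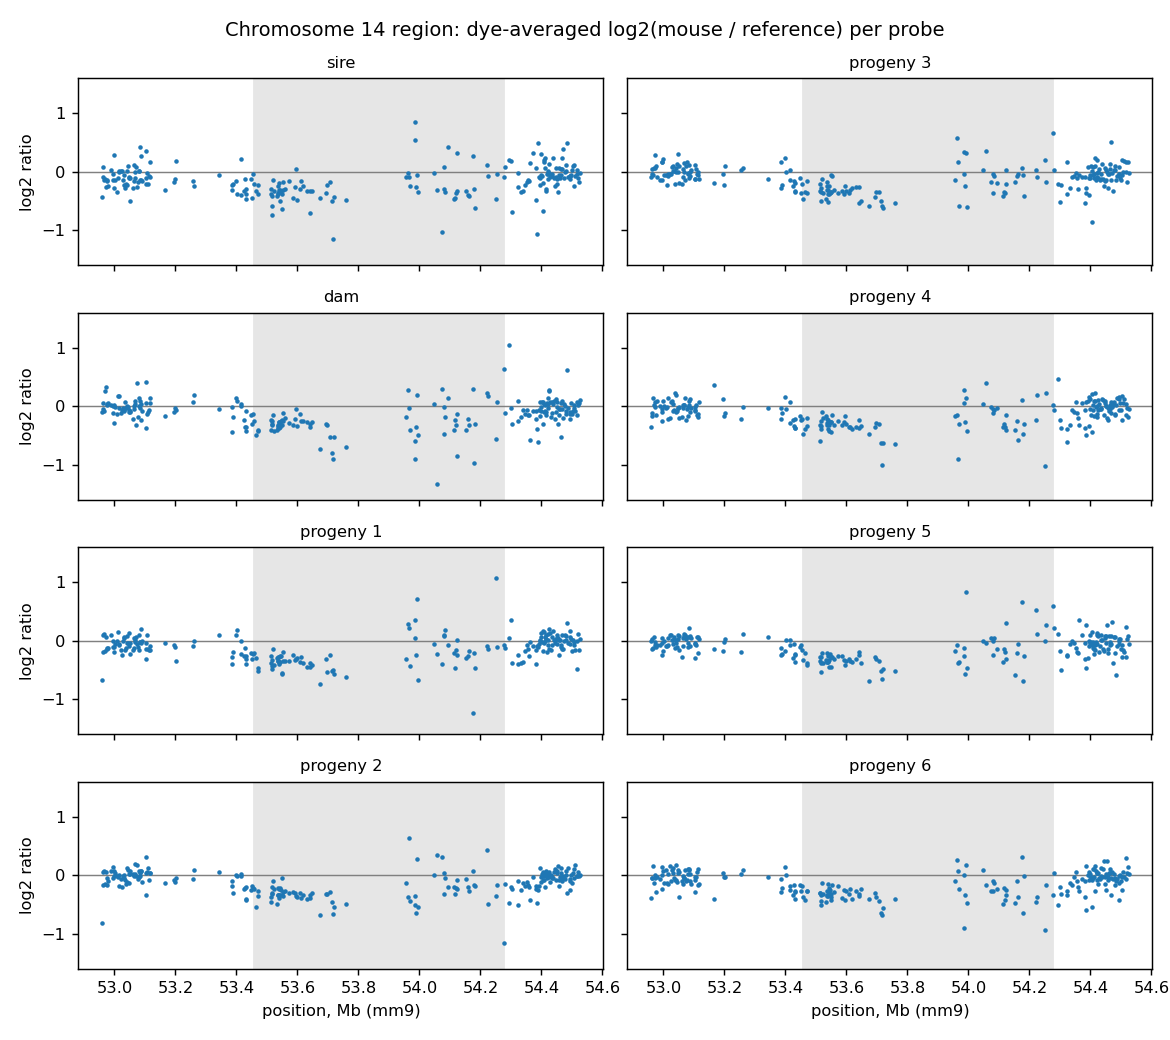
Dye-averaged log2 ratio of each probe around the chromosome 14 region (grey, mm9 position in Mb) in the 8 mice. The means over the grey interval were -0.23 to -0.30 in the 8 mice. They were weaker in its last part, with -0.03 in progeny 5 there.

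Against the reference, the 100-kb windows that differed most lay in the chromosome 14 and chromosome 4 regions. Of 23614 autosomal windows of 100 kb, 9 were higher and 221 lower than the reference at an adjusted p of at most 0.05 (limma, intercept over 8 mice). These counts moved with the processing, to 27 and 1503 from the series table, 14 and 50 by window medians, 9 and 98 without centring and 33 and 205 with normexp. With only 1 dye orientation they were 4516 and 3520 (mouse in Cy3) and 2842 and 7377 (mouse in Cy5). In the main setting their median absolute log2 ratio was 0.04, and 11 of them reached 0.1 and 7 reached 0.2. Of these 7, 5 lay on chromosome 14, and 2 on chromosome 4 from 101100001 and 101200001, at 0.47 and 0.41, without the same sign in all 8 mice. Of the 10 windows named by rule, 7 lay on chromosome 14 between 53300001 and 54400000, from -0.11 to -0.55, with adjusted p values between 7.9e-15 and 0.000219 (limma). The others were 1 window of 2 probes on chromosome 6 from 3000001, at -0.11, and 2 windows on chromosome 7 from 39200001 and 55300001, at -0.10 and -0.07. The 8 mice are 1 family set against 1 reference male, so the p values measure how repeatable a ratio was among related mice. A feature of the reference DNA or of the probes would enter all 8. With scan day as a random block, 101 windows were higher and 959 lower, at an estimated correlation within days of -0.13. The count of lower windows was 129 without the sire, 25 without progeny 1, 371 without progeny 2, 48 without progeny 4 and 24 without progeny 6, and that of higher ones 18 without the dam, 3, 17, 2 and 2 without progeny 1, 2, 4 and 6.

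Between progeny and parents, no window passed the threshold. At an adjusted p of 0.05, 0 windows were higher and 0 lower in the 6 progeny than in the 2 parents (limma), with a smallest adjusted p of 0.0867. At an unadjusted p under 0.05 there were 1503 windows, against 1181 that chance gives. In simulated windows with the same spread, a difference of 0.1 was called in 84% of windows and of 0.05 in 8%. Without the dam, 69 windows were higher and 28 lower, the sire then standing alone for the parents and assumed to vary like the progeny. Scan day as a random block gave 2 higher and 2 lower, as did leaving out the sire, and 1 was higher without progeny 1, 1 higher without progeny 6 and 1 lower without progeny 3.

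Single probes past the threshold in both dye orientations were more frequent in the dye direction than in the mouse direction. Between 315 and 597 probes per progeny, with a mean of 456 ± 109 (SD, n = 6), had an absolute log2 ratio of at least 0.5 toward the same mouse direction on both arrays, against 2360 in the sire and 1568 in the dam. Past 0.5 in the same dye direction were 1640 ± 617 probes in the progeny (SD, n = 6), 4633 in the sire and 2876 in the dam. The dye-direction count was the higher in 8 of 8 mice (p = 0.00781, exact sign-flip test, two-sided, the smallest p that 8 mice allow). Progeny had a lower mean of mouse-direction probes than parents (p = 0.0714, exact permutation test, two-sided by doubling the smaller tail, the smallest p this gives for 6 mice against 2). Counting absolute differences gave p = 0.0357 (exact permutation test), so the call rests on this convention. The parents' arrays had the higher noise, and with normexp the difference was -13.3 probes (p = 0.643, exact permutation test). Normexp also shrank the X and Y ratios, and the cut of 0.5 was kept on that scale.

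The scan for runs of neighbouring probes called 824 autosomal intervals over the 8 mice, and a mean of 715 with the probe order shuffled. The sire had 158 calls, the dam 158 and the progeny 84.7 ± 22.2 (SD, n = 6), with 619 losses and 205 gains in all. In 5 shuffles of the autosomal probe order, which removes every true run, the same scan called 698 to 723 intervals. The noise SD was estimated anew from the shuffled order. A further shuffle with planted intervals, scored against the noise SD of the unshuffled profiles, gave 793 calls outside those intervals. The size of the excess over shuffling therefore depends on which noise SD is used. The excess differed between mice, from 158 calls against a shuffled mean of 122.6 in the sire and 116 against 78.4 in progeny 1 to 63 against 66.0 in progeny 4 and 103 against 103.0 in progeny 6. Runs of 3 or 4 probes numbered 730 against a mean of 685 after shuffling, runs of 5 or more 94 against 29.6, and runs of 10 or more 29 against 0. The 29 count the same locus once per mouse, as with the chromosome 4 gain in 7 mice and the chromosome 14 loss in 8. Joined over mice, 13 regions had 10 probes or more. Calls were more frequent than on the dye-direction track in 8 of 8 mice, 824 against 263 in total (p = 0.00781, exact sign-flip test, two-sided). With a mean of at least 0.5 required, the excess was 6.25 per mouse and no longer passed (p = 0.484, exact sign-flip test). Each track was scored against its own noise, and a wider track needs a larger mean for the same score. The SD over autosomal probes was larger on the dye-direction track in each mouse, with 0.192 against 0.162 in the sire. The counts of regions by family class hold the calls of 3 or 4 probes too. Calls per progeny minus calls per parent were -73.3 (p = 0.0714 by doubled tail, 0.0357 by absolute differences, exact permutation tests). The difference was 0.333 with normexp (p = 1), -2.33 with only probes well above background (p = 0.929) and -2.67 at a score of 8 (p = 0.643, exact permutation tests). In a new scan that allowed only runs of at least 10 probes, which made 5.38 calls per mouse, it was -4.17 (p = 0.286, exact permutation test). Calls per mouse were far fewer than in the main scan with normexp, with only probes well above background and at a score of 8.

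**Figure D4:**
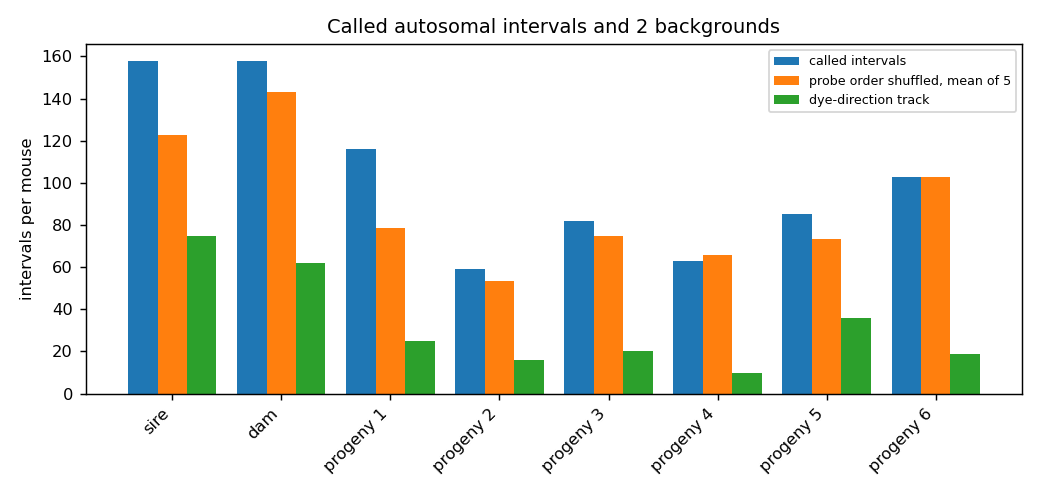
Called autosomal intervals per mouse, the mean over 5 shuffles of the probe order, and calls on the dye-direction track, as bars from 0. The 8 mice together had 824 calls, a mean of 715 after shuffling and 263 on the dye-direction track.

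By family class, calls of different mice that overlapped formed 737 regions, of which 2 were carried by all 8 mice, 220 by parents and progeny, 305 by progeny only and 210 by parents only. In the same order these were 4, 37, 28 and 15 with normexp, and 66, 81 and 46 for the last 3 with only probes well above background. A carrier needs no call of its own, and most of the 220 left their class when carriers were set by own call. Only 13 of the 737 had 10 probes or more, and 667 had 3 or 4. Of the 8 regions named by rule among those of parents and progeny, 7 were losses. A 3-probe region on chromosome 3 from 25417435 to 25432738 lay at -1.65 in the dam and at -1.63, -1.49, -1.62 and -1.55 in progeny 3, 4, 5 and 6, but at 0.04 in the sire and at 0.05 and -0.02 in progeny 1 and 2. Regions on chromosome 6 from 104238274, chromosome 9 from 35855832 and chromosome 3 from 132546474 had the same carriers, with values from -0.42 to -0.82 in the dam and from -0.33 to -0.87 in progeny 3 to 6. The same 4 progeny lay lowest, at -0.66 to -0.86, on chromosome 11 from 112957750 and chromosome 5 from 123596881, where progeny 1 also passed -0.20. Progeny 3 to 6 were also those with X medians of 0.90 to 0.93, and of 17 regions carried by the dam without the sire and by exactly 4 progeny, 15 had these 4. On chromosome 5 from 87762473 the dam had -0.97 and progeny 5 had -0.51, against -0.16 to 0.05 in the other progeny. The value of the dam there was -0.12 with normexp and -0.13 with only probes well above background.

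Regions found in progeny only were short and mostly single. The strongest was a loss over 3 probes on chromosome 1 from 193319436 to 193323042 in progeny 1, at -0.92, with -0.84 and -1.01 on its 2 arrays and -0.04 to 0.07 in the other 7 mice. Other named losses lay on chromosome 3 from 117858167 in progeny 6 (-0.62, with the dam at 0.44), on chromosome 10 from 71801394 in progeny 1 (-0.62) and on chromosome 14 from 54223715 in progeny 2 (-0.31 over 17 probes, across the right end of the chromosome 14 region, with -0.25 in progeny 6). On chromosome 14 all 8 mice lay below the reference, with -0.14 in the sire, -0.03 in the dam and -0.17 in progeny 4. The 100-kb window from 54300001, which this loss partly covers, had a mean of -0.15 over the 8 mice. The class of this loss thus rests on the carrier threshold of 0.2. Named gains lay on chromosome 1 from 75419466 in progeny 4 (0.68), on chromosome 19 from 17433516 in progeny 6 (0.59) and on chromosome 5 from 24601080 in progeny 4 (0.57). A further gain lay on chromosome 11 from 76357341 in progeny 3 (0.77, with 1.11 and 0.43 on its 2 arrays). There progeny 4 read 0.29 and progeny 6 read -0.3. Of these 8 regions, 4 fell under 0.2 in size with normexp, to -0.09 on chromosome 3, -0.10 on chromosome 14, 0.03 on chromosome 11 and 0.05 on chromosome 19. With only probes well above background, chromosome 3 read -0.13, chromosome 19 read 0.02 and chromosome 11 had no value. The loss on chromosome 1 from 193319436 read -0.74 and -0.92 in these settings. Against both parents, 266 of the 305 regions passed an adjusted p of 0.05 in 10000 random runs of as many probes, as did 25 of 28 with normexp and 77 of 81 with only probes well above background. That test takes no account of the search that picked the regions over the genome. Regions carried by 1 animal alone numbered 37.3 ± 8.41 per progeny (SD, n = 6) and 98.0 per parent (p = 0.0714 by doubled tail, the smallest it gives, and 0.0357 by absolute differences, exact permutation tests, two-sided). The parents' arrays were noisier and scanned on another day. With the probe order shuffled, the sire and dam also had more calls (means of 122.6 and 143.2) than the progeny (53.4 to 103.0). Generation and array noise cannot be told apart in this difference.

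**Figure D5:**
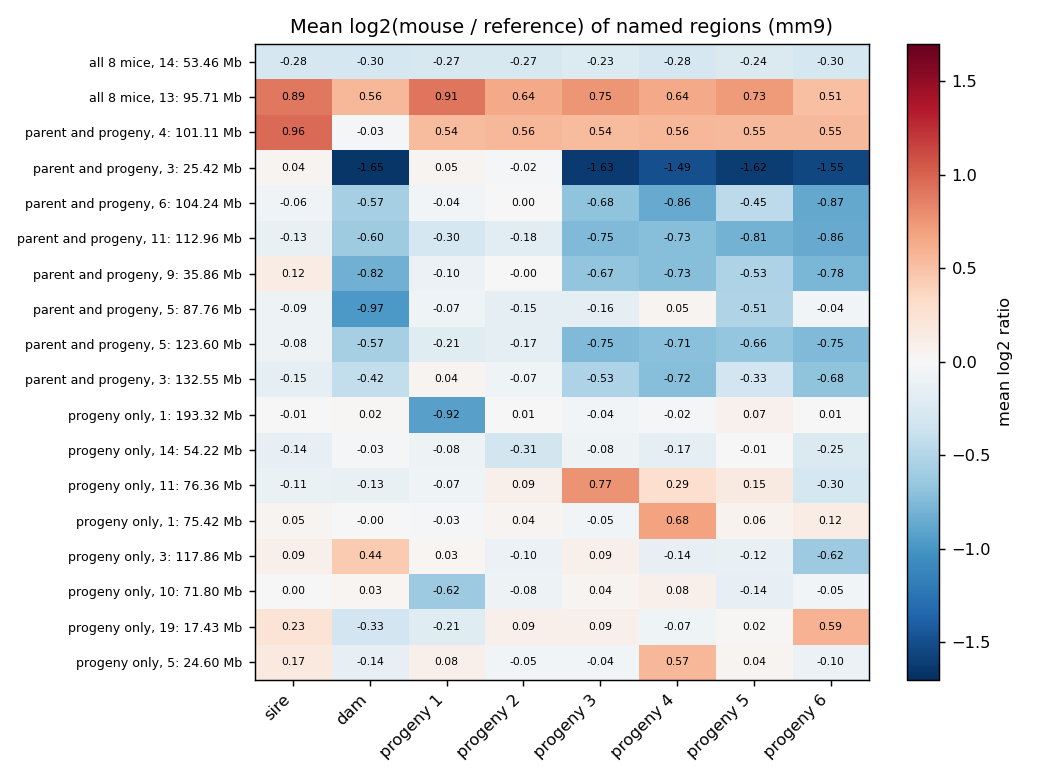
Mean log2 ratio of mouse over reference of the regions named by rule in all 8 mice, in parents and progeny, and in progeny only, with chromosome and start (mm9). The chromosome 4 region read 0.96 in the sire and 0.54 to 0.56 in the progeny, and the chromosome 3 region from 25417435 read -1.65 in the dam.

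Regions of parents only were single-animal calls in the main. The highest score was a gain over 3 probes on chromosome 12 from 118163399 in the sire, at 0.93, with 0.26 in the dam and -0.02 ± 0.08 in the progeny (SD, n = 6). The other named losses lay in the sire on chromosome 17 from 19900491 (-0.76), chromosome 8 from 87828418 (-0.74), chromosome 2 from 90750524 (-0.73, with the dam at -0.30) and chromosome 18 from 42654382 (-0.70, with the dam at -0.31). A loss in the dam lay on chromosome 5 from 11931734 (-0.70, with the sire at 0.58). Named gains lay on chromosome 10 from 113410708 in the dam (0.60) and on chromosome 4 from 136354481 in the sire (0.72, with 0.24 and 1.2 on its 2 arrays). All had 3 or 4 probes. With normexp, 7 of the 8 fell to between -0.08 and 0.09, and the chromosome 4 gain read 0.50. Normexp also shrank the X and Y ratios of the dam, so this fall alone does not show that the calls were false. The same 7 lay between -0.16 and 0.18 with only probes well above background. Of the 8, 6 were led by the sire and 2 by the dam.

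Over all sizes, regions carried by exactly 1 parent reached fewer progeny than the 50% of a heterozygous variant. There were 388 such regions, which gave 2328 region and progeny pairs. Of these pairs, 326 were carried, or 14% (exact 95% interval 12.6 to 15.5%, p = 2.84e-293, exact binomial test, two-sided). A region could enter through the call of a progeny, with no call in the parent. That progeny then counted as carried, so the share is not a pure rate of transmission. The test takes the pairs as independent, which they are not. The interval leaves out the moves with the processing given below. The share was 10.3% for regions of the sire and 17.4% for those of the dam. The dam's include 15 regions carried by exactly progeny 3 to 6, the progeny at her X level, which raise her share. Over both parents the share was 14.4% over 3 or 4 probes, 11.2% over 5 probes or more and 28.3% over 10 probes or more (17 of 60 pairs, exact 95% interval 17.5 to 41.4%). For the dam's regions of 10 probes or more it was 41.7% (exact 95% interval 22.1 to 63.4%, p = 0.541, exact binomial test), with too few pairs to tell it from 50%. Of these 10 carried pairs, 9 came from 3 neighbouring gains on chromosome 8 between 102125282 and 102245478. The first ended at 102155515 and overlapped the second, which began at 102148548, so 1 gain may be counted more than once. All 10 pairs lay in progeny 3 to 6, those with X medians of 0.90 to 0.93. For the sire's regions of 10 probes or more the share was 19.4% (7 of 36 pairs), and 6 of the 7 came from the chromosome 4 gain. There the sire lay at 0.96 and all 6 progeny lower, at a mean of 0.55. A heterozygous gain passed on whole would read the same in carrying progeny as in the sire. These values therefore argue against a heterozygous gain in the sire, and so against 50% as the expected share for this gain. The share over all regions moved with the processing, to 39.2% with normexp, 31.6% with the mouse in Cy5 alone, 24.4% with only probes well above background and 2.4% with carriers by own call. Regions near each other are not independent, and chance calls of a parent enter the denominator.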

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

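Tests of dye bias at both settings, of the spread of mice without a call, of the carriers by X level and of the chromosome 3 loss were chosen after their results were seen, and the shuffling was added after seeing the data. Of 53 sets of 6 progeny values, 7 held an animal far from the other progeny, where chance gives about 2.6. Regions picked for a strong call in 1 animal tend to stand out by construction.

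The values far from the other progeny were -0.92 in progeny 1 on chromosome 1 from 193319436 and 0.68 in progeny 4 on chromosome 1 from 75419466. They also included -0.62 in progeny 6 on chromosome 3 from 117858167 and -0.62 in progeny 1 on chromosome 10 from 71801394. Progeny 4 had 0.57 on chromosome 5 from 24601080 and progeny 5 had -0.51 on chromosome 5 from 87762473. The chromosome 17 median of progeny 4 was 0.008, above a range of -0.00 to 0.002 in the others, and far below any change of copy number. With normexp, progeny 6 read -0.09 on chromosome 3 from 117858167, and the dam, which led the call on chromosome 5 from 87762473, went from -0.97 to -0.12.

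Short runs of 3 or 4 probes made up most calls. Shuffled probes gave a mean of 685 of them against 730 observed (714.6 against 824 over all sizes), which is consistent with chance runs of heavy-tailed probe noise as the main source. The dye-direction track gave 227 short calls against 730, and 233 against 274 with a mean of at least 0.5 asked for. Each track was scored against its own noise, so the tracks were not held to an equal bar. A dye effect equal on both arrays cancels in the averaged profile, so neither pair of counts measures dye bias in these calls. Whether dye bias contributed was therefore not decided. Inherited small variants would reach about 50% of progeny. Short regions of 1 parent reached 14.4% (exact 95% interval 12.9 to 16%), which argues against such variants as the main source. This share also counts progeny whose own call brought in the region, so it is not a pure rate of transmission. Mice without the call varied 1.94 times as much as random runs, but shuffled calls, added once that ratio was known, gave 1.94 too, so whether neighbouring probes vary together remains open.

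Several autosomal regions followed the X and Y levels of the mice. Of 17 regions carried by the dam without the sire and by exactly 4 progeny, 15 had progeny 3 to 6, the progeny at the dam's X level, and no other set of 4 had more than 1. This may come from probes that also match sex chromosome sequence. An autosomal loss inherited from the dam was argued against on chromosome 3 from 25417435, where a dam at -1.65 would leave every progeny short of a copy, and the highest progeny lay at 0.05. Probe sequences were not matched to a genome here, so this remains a hypothesis, and no biological explanation other than inheritance was tested.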

How the results depend on the processing

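The shuffled probe order and the windows in place of genes were chosen after seeing the data, as were all counts of windows here and the permutation by absolute differences. Of the values under alternatives for the main results, 307 were counted as kept, 115 moved, 1 lost its call, 2 gained one and 1 turned. With a test, kept means the same direction and side of the threshold. A difference can then shrink by far, as that in aberrant probes of progeny minus parents did with normexp. For counts without a test it means a value within a fixed ratio of the main one. For X and Y it means a value within the pooled spread of the 2 arrays. The cause of a move was not tested unless stated. Of the values of the 26 named regions, 171 stayed within the spread of their 2 arrays, 36 moved and 0 turned. With normexp 12 of 26 fell under 0.2 in size, and with only probes well above background 10 of 25, as chromosome 12 from 118163399 went from 0.93 to 0.09 and 0.14, while 1 had no value. The chromosome 4 gain in the sire ran from 0.83 (normexp) to 0.97 and the chromosome 14 loss in progeny 6 from -0.24 (normexp) to -0.31, beyond the spread of the 2 arrays in 7 and in 3 of 8 settings; in the sire that spread was 0.00. Counting absolute differences, which is another definition of the same test, gave p = 0.0357 for progeny minus parents in aberrant probes (-1508) and calls (-73.3) (exact permutation). With normexp, aberrant probes per mouse were 83, calls per mouse 19.8, calls of progeny minus parents 0.333 (turned, exact permutation p = 1) and regions 4 in all 8 mice, 37 in parents and progeny, 28 in progeny only (25 past the difference test) and 15 in parents only, with 33 windows above the reference. X then read 0.67 in the dam and 0.73, 0.79, 0.73 and 0.83 in progeny 3 to 6, and Y -0.28 and -0.32, -0.43, -0.34 and -0.35. Normexp thus also shrank the X and Y ratios, and all cuts were kept on that scale. A fall with normexp does not by itself show a false call. With the mouse in Cy5 alone, which keeps the dye effect, aberrant probes were 23992, regions 451 in parents and progeny, 203 in progeny only and 99 in parents only, windows 2842 above and 7377 below the reference and 4 above in progeny over parents, X -0.07 in the sire and 0.88 in progeny 5, and Y -2.06 in the dam, -0.19 in progeny 1 and -2.02 in progeny 4. With the mouse in Cy3 alone these were 22319 probes, 156 progeny-only regions (155 past the test), 4516 and 3520 windows and 3 above in progeny over parents, X 0.02 in the sire and 0.02 in progeny 1, and Y -2.04 in progeny 3 and -2.34 in progeny 5. Only probes well above background, which are fewer, gave 468 aberrant probes, 32.8 calls, 66, 81 (77 past the test) and 46 regions of parents and progeny, progeny only and parents only, and 17 windows above the reference. Thresholds of 0.3 and 0.8 gave 6866 and 89.9 aberrant probes. In the same order of calls and regions, at least 5 probes gave 34.9 calls, 52, 77 (62) and 93; at least 10 probes 5.38 calls, 1 region in all 8 mice, 9, 3 (3) and 10; a score of 8 20.5 calls, 54, 39 (37) and 20; a mean of 0.5 36.1 calls, 4 in all 8 mice, 88, 34 (34) and 114. At a mean of 0.5, calls exceeded the dye direction by 6.25 and no longer passed (exact sign-flip p = 0.484). Without a condition on single orientations there were 155 calls and 502 progeny-only regions (431). Carriers at 0.1 gave 392 regions of parents and progeny and 102 of parents only. Carriers at 0.3 gave 1 in all 8 mice and 100 of parents and progeny. With carriers by own call, 22 were of parents and progeny. Windows above and below the reference were 101 and 959 with scan day as a random block, 27 and 1503 from the series table, 14 and 50 by medians and 32 and 86 for single probes; 98 lay below without centring and 14 above with at least 5 probes. Progeny over parents gave 2 and 2 with the block, 4 and 2 for single probes and 1 below from the series table. Leaving out each mouse gave 614 to 907 aberrant probes, -1453 to -1202 against the dye direction and -1904 to -1112 against parents, 95.1 to 109 calls, 66.4 to 74.0 against the dye direction and -79.6 to -68.2 against parents, 2 to 3 regions in all 8 mice, 108 to 202 of parents and progeny, 234 to 378 of progeny only (206 to 346), 99 to 234 of parents only, 13.1 to 19.6% transmission, 2 to 18 and 24 to 371 windows above and below the reference, and 0 to 69 and 0 to 28 of progeny over parents. Regions of parents and progeny were 129 without the sire and 108 without the dam, and parent-only ones 99 and 112, since 1 parent is then missing. Windows below the reference were 129 without the sire, 25, 371, 48 and 24 without progeny 1, 2, 4 and 6, those above 18 without the dam and 3, 17, 2 and 2 without those progeny, and the 69 and 28 came without the dam. Transmission, taken as the share of region and progeny pairs carried, ran from 2.4 to 39.2% under the alternatives, below 50% in each. The spread against which X and Y were judged was pooled over the 8 mice, a choice made after single pairs gave spreads of 0. In 1 shuffle for each setting, shuffled probes gave 87.2 calls per mouse, 18.5 with normexp, 25.0 at 5 probes, 0.5 at 10 and 17.1 at a score of 8. The gene lists were not run, since no gene names were used. No paired analysis was possible because sire and dam are 1 animal each. Dimmer parental arrays limit what can be said of short runs in the parents.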

Other observations

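All tests of the chromosome 14 region were chosen after its values were seen. The region lay at -0.27 in the mean of the 8 mice (SD 0.03), which argues against a single-copy germline difference of the reference animal over the whole region, as the chromosome 4 step would predict -0.55. Of 3 equal parts the last was the weakest in all 8 mice, by a mean of 0.16, but it begins near or past the end of the longest call in the sire and progeny 1 to 5. Shorter losses were called past that end in the sire and progeny 1, 2 and 4. Inside the span that the longest calls of all 8 mice share, the windows from 53500001, 53600001 and 53700001 had means of -0.31, -0.36 and -0.55, over 27, 10 and 5 probes. They differed more than with probe positions shuffled (permutation p = 0.0001, the smallest that 10000 shuffles give), by 0.15 to 0.40 in the 8 mice, which argues against an even change that ends earlier in most mice as the whole account. Whether the amount of DNA or the response of the probes differed along the region, a change in part of the cells and repeated sequence were not tested.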
